A study of Mus musculus with 17 samples.

How the data were processed

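Per the labels' protocols, epidermal cells came from C57BL/6 mice aged 3 months that carry an EGFP-CreERT2 cassette at Lrig1, Lgr5 or Lgr6 and had been treated with 4-hydroxytamoxifen. Control mice held 1 floxed Pelo allele (Pelo fl/+, labelled WT) and mutant mice held a floxed pair (Pelo fl/fl, labelled Pelo -/- here and below). For each population 1000 GFP-positive cells were collected by flow cytometry, and libraries were made by the full-length method that the labels cite to Picelli and colleagues. The submitters' processing notes name STAR and edgeR and the genome builds GRCm38 and mm10, without versions. Which tool produced the counts, the annotation release, whether strand was used and how reads shared between genes were treated are not given in the sources used here.

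The deposited table held whole-number counts per gene for 17 libraries, used as deposited. It listed 48820 gene identifiers, and every column was matched to 1 labelled sample. Against GENCODE M21 on GRCm38, the annotation supplied for this work, 40606 identifiers matched with their version and 48058 without it. The other 762 kept their identifier as name, and they took between 0.110% and 0.157% of the counts of a library. Another 124 identifiers share a symbol with a second one and were kept apart. All tests used the raw counts. No library was a copy of another in its own group, since the smallest chi-square per degree of freedom between a pair of replicates was 45.1. Pairs across groups were not compared in this way.

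Groups were taken from the sample titles and characteristics, as population and genotype. The WT Lrig1 group had 2 libraries and each of the other 5 groups had 3. The series text speaks of triplicates for each condition, and no more than these of WT Lrig1 were among the samples used here. Replicate numbers were read from the titles. The labels do not say that replicates came from separate animals, so p-values here measure the spread between these samples. Total counts were 21694454 and 26827421 in WT Lrig1, and 22471651, 18937127 and 13333497 in Pelo -/- Lrig1. They were 19723018, 21408579 and 28098841 in WT Lgr6, and 21268967, 18338235 and 21721255 in Pelo -/- Lgr6. In WT Lgr5 they were 11223457, 11261870 and 9647507, and in Pelo -/- Lgr5 17219054, 10501324 and 11769316.

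All 17 libraries entered 1 edgeR quasi-likelihood fit with robust dispersions and 1 coefficient per group. Library sizes were scaled by TMM, whose factors lay between 0.990 and 1.91 in the Lgr5 libraries and between 0.688 and 0.964 in the others. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 30405 genes. The common dispersion was 0.537. There were 9 comparisons, namely Pelo -/- against WT within each population, the 3 differences of those effects between populations, and the 3 pairs of WT populations. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 in edgeR, computed within each comparison. Standard errors of log2 fold changes were computed as the size of the fold change over the square root of F. CPM values are TMM-scaled, and group values are means with SD over libraries. A gene with no count in any library of a group has no finite fold, so a lower bound is given from a floor of 3 counts over that group. Such floors cover counting error only.

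There were 42 gene lists, 34 of processes and 8 of markers of cell types, written from general knowledge before the data were examined. All 42 had at least 5 members among the tested genes. Each was tested with camera in limma on voom values with a preset correlation of 0.01 between genes, and adjusted over the 42 lists within a comparison. Each call is given with the adjusted p obtained when the correlation was estimated from the data. Within a list, members were also counted after adjustment over the list alone.

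Genes to be named followed a rule set before the data were examined. In each Pelo -/- comparison these were the 10 genes per direction with the largest fold among those called, with a mean log2 CPM of at least 3 over the compared groups, groups that do not overlap, and a symbol that is not a predicted or non-coding identifier. Where no gene qualified in a direction, the 3 with the smallest p were named as values. Differences between populations used 5 per direction without the condition on overlap, and WT comparisons used 8. Pelo, Itga1, Lrig1, Lgr5 and Lgr6 were read in every comparison. For each list called, up to 4 members with the smallest adjusted p in the direction of the call could be named. In Pelo -/- comparisons up to 3 members with the smallest p were also read for each of 6 lists on division, ribosomes, mTOR, differentiation and wounds, together with any member of the rescue list that was called. The text prints those it needs, in order from the smallest p within a list. A few genes that this rule reached are not reported here.

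Alternatives written before the data were examined were RLE size factors, no filter on low counts, a minimum mean CPM of 5 (11061 genes), DESeq2, limma-voom with sample quality weights, a fit of only the libraries compared, the replicate number as a block, a minimum 2-fold change, and leaving out each library in turn. For lists they were an estimated correlation, the fry rotation test, the replicate block and leaving out each library. The fry test asks whether the genes of a list move one way, and does not compare them with other genes as camera does. DESeq2 gives no adjusted p to some genes, and these were left uncalled there. Chosen after the data were seen were sex as a covariate, read from Xist and 4 Y-linked genes, protein-coding genes only, a fit of the 11 Lrig1 and Lgr6 libraries, the populations compared in the Pelo -/- libraries, and a table without 12 predicted genes of satellite-like sequence. Similarity of the Pelo -/- effects between populations was read as correlations of log2 fold changes across genes, which are not independent replicates.

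The fit was first tried on simulated counts of 28393 genes with the libraries and dispersions of the study, in which 200 genes were changed. The changed genes were drawn from those at a mean log2 CPM of at least 3, so the rates do not cover lower genes. Each gene had 1 dispersion for all populations. In the Lrig1 design 0% of 2-fold, 26% of 4-fold, 66% of 8-fold and 96% of 16-fold changes were called. In the Lgr5 and Lgr6 designs these were 4%, 38%, 84% and 98%, and 4%, 38%, 84% and 90%. Of the calls, 5.05%, 7.44% and 6.90% were of unchanged genes in the Lrig1, Lgr5 and Lgr6 designs. In a separate simulation of 28449 genes in the Lrig1 design, a list of 40 genes raised by 0.6 (log2) was called by camera, and 0 of 40 unchanged lists were. Genes were drawn independently there and lists were filled at random. The simulation thus cannot show how often camera calls unchanged lists whose genes are correlated.

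Sequence-level reads, splice junctions and the exon that was deleted were not analysed here. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.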

Results

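Epidermal stem cells of mice were sorted from 3 places of the hair follicle by the green fluorescent protein that each line carries at Lrig1, Lgr5 or Lgr6. Lrig1 is used as a marker of the upper follicle, Lgr6 of the isthmus, and Lgr5 of the lower bulge and hair germ. The same alleles carry an inducible Cre recombinase, so that treatment with 4-hydroxytamoxifen deletes floxed Pelo in the marked cells. Pelo encodes a factor that frees ribosomes stalled on messenger RNA, and the comparisons asked which genes and gene groups differed with its deletion in each population. Per the labels, libraries held 1000 sorted cells from mice of 3 months, with Pelo fl/+ mice as controls (labelled WT) and Pelo fl/fl mice as mutants (labelled Pelo -/-). The deposited counts covered 17 libraries, 2 of WT Lrig1 and 3 of each of the other 5 groups.

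Total counts ran from 9647507 to 28098841 per library, with a median of 18937127. The 6 Lgr5 libraries held 9647507 to 17219054. Predicted genes of satellite-like sequence took 10.02%, 4.02% and 25.0% of the counts of the WT Lgr5 libraries, 1.69%, 6.34% and 9.26% in Pelo -/- Lgr5, and 0.233% to 2.79% in the 11 others. Genes of the mitochondrial genome took 3.69% to 15.3% in Lgr5 and 4.66% to 7.68% elsewhere. Spearman correlations of replicate libraries across genes, which are not independent replicates, lay between 0.729 and 0.806 in Lgr5 and between 0.887 and 0.926 elsewhere.

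Pelo counts did not separate the genotypes in any population. In Lrig1 cells Pelo stood at 3.82, 0.483 and 0.857 CPM in the Pelo -/- libraries and at 6.05 and 3.72 CPM in WT (log2 fold change -1.49 ± 0.83, edgeR adjusted p = 1, n = 3 and 2). In Lgr5 cells it stood at 11.8, 23.6 and 15.1 CPM against 17.4, 5.90 and 17.3 CPM (0.31 ± 0.74, edgeR adjusted p = 1, n = 3 and 3). In Lgr6 cells it stood at 3.10, 4.94 and 4.195 CPM against 4.12, 5.39 and 2.02 CPM (0.09 ± 0.75, edgeR adjusted p = 1, n = 3 and 3). Pelo lies on the minus strand of chromosome 13 from 115088355 to 115090186, inside Itga1 on the same strand, with 0 bp shared between their exons. Itga1 had log2 fold changes of 1.77 ± 1.52 in Lrig1, -0.73 ± 1.26 in Lgr5 and -2.81 ± 1.40 in Lgr6 cells (edgeR adjusted p = 1 in each). Which part of Pelo the deletion removes is not given in the sources used here, so gene-level counts do not measure how complete the deletion was. Counting by strand could not separate intronic reads of Itga1 from reads of Pelo, since the genes share a strand.

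Lgr5, a receptor for R-spondins, stood at 276, 570 and 364 CPM in WT Lgr5 libraries and at 550, 467 and 476 CPM in Pelo -/- Lgr5. It stood at 27.99 and 8.46 CPM in WT Lrig1 and at 1.73, 24.6 and 0.414 CPM in WT Lgr6. Lrig1, which encodes a negative regulator of growth factor receptors, averaged 40.5 ± 1.75 CPM (SD) in WT Lrig1, 50.6 ± 8.18 CPM in WT Lgr6 and 14.7 ± 3.96 CPM in WT Lgr5. Its level in Pelo -/- Lrig1 was 37.7, 7.42 and 11.6 CPM against 39.3 and 41.7 CPM in WT (log2 fold change -1.10 ± 0.54, edgeR adjusted p = 1). Lgr6, a related receptor, averaged 83.5 ± 35.6 CPM in WT Lrig1, 145 ± 60.1 CPM in WT Lgr6 and 72.0 ± 47.2 CPM in WT Lgr5, and no pair of WT populations differed in it (edgeR adjusted p = 0.212 for Lgr6 against Lgr5).

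**Figure D1:**
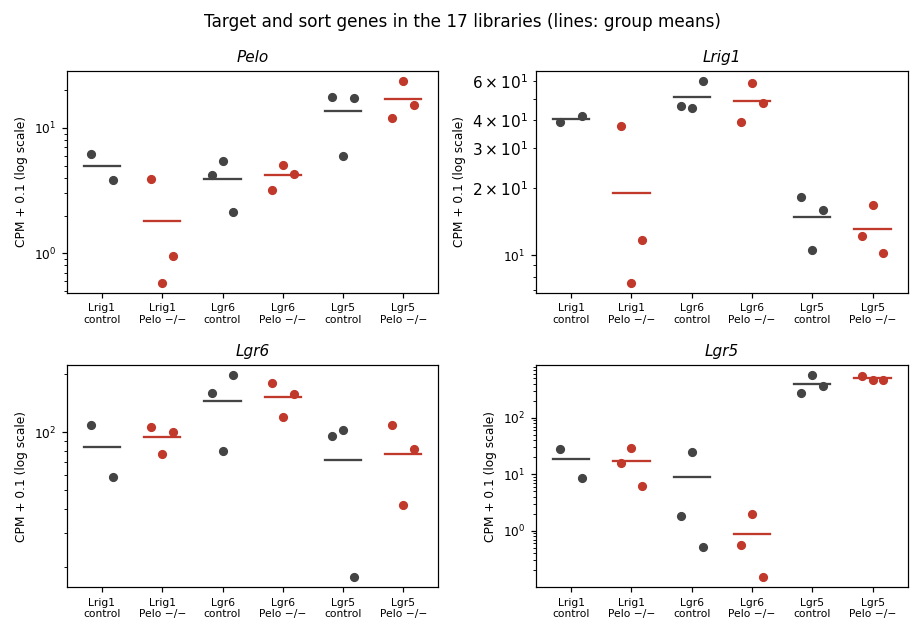
Levels of Pelo and the 3 sort genes in each library, as CPM plus 0.1 on a log axis, with WT in black, Pelo -/- in red and lines at group means. Lgr5 averaged 403 ± 151 CPM in WT Lgr5 and 8.93 ± 13.6 CPM in WT Lgr6 libraries (SD, n = 3 and 3).

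Control Lrig1 and Lgr5 cells differed in many genes, among them genes of keratinocytes. Ly6d, a surface antigen of the Ly6 family, was higher in Lrig1 cells by 12.04 ± 0.98 (log2, SE; 4717 ± 678 against 1.12 ± 0.501 CPM, SD, n = 2 and 3; edgeR adjusted p = 1.73e-07). Higher too were the suprabasal keratin Krt77 by 9.43 ± 1.31, the interleukin-1 antagonists Il1r2 by 9.37 ± 1.00 and Il1rn by 9.22 ± 0.74, and Krtdap, a gene of differentiating keratinocytes, by 8.87 ± 1.10. Lower in Lrig1 cells were Fam171b by -6.13 ± 1.26 (1.49 ± 1.97 against 103 ± 34.6 CPM), Nhs by -5.04 ± 0.81, the neuronal adhesion gene Lrrn3 by -4.99 ± 0.92 and the collagen gene Col8a2 by -4.98 ± 0.83. Each of these genes kept its call without any 1 library. Other genes named by the rule did not, since without WT Lrig1 replicates 1 and 2 the adjusted p of Kcnk2 was 0.0606 and 0.0824, of the BMP antagonist Nog 0.139 and 0.0980, of Mme 0.175 and 0.283, and of Pdzrn4 0.189 and 0.195. Lgr5 was lower by -4.47 ± 1.53 without passing (edgeR adjusted p = 0.0809).

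In this comparison edgeR called 3369 genes, 2765 higher and 604 lower in Lrig1 cells, a share of 82.1% higher. With a minimum mean CPM of 5 the split was 1750 against 1412, or 55.3% higher. The median log2 fold change of all genes was -0.99 under TMM and -1.36 under RLE, and -0.06 at that minimum, so the share called higher changed with the filter. DESeq2 called 2839 higher and 4521 lower, and limma-voom 3393 and 1851. Without WT Lrig1 replicate 1 or 2 edgeR called 2132 or 1294 genes.

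Keratinocyte, histocompatibility and follicle groups separated Lrig1 from Lgr5 control cells. Of 8 interfollicular keratinocyte markers 7 were called higher (7 adjusted over the list alone; median 6.11; camera adjusted p = 1.53e-11, adjusted p = 0.00167 with an estimated correlation), among them Ly6a by 9.92 ± 0.65 and the basal keratin Krt14 by 4.43 ± 0.48 (6886 ± 1568 against 319 ± 163 CPM). Of 20 histocompatibility genes 14 were called higher (15 higher and 1 lower adjusted over the list alone; median 2.92; camera adjusted p = 4.30e-13, adjusted p = 0.00167 with an estimated correlation). These included the class II chain Cd74 by 6.60 ± 0.61 (79.0 ± 61.6 against 0.805 ± 0.264 CPM) and the class I gene H2-T22 by 5.25 ± 0.53. Spinous and granular genes ranked higher, 20 called higher and 2 lower of 44 (23 and 3 adjusted over the list alone; camera adjusted p = 1.62e-06, adjusted p = 0.0886 with an estimated correlation). They were led by Casp14, higher by 7.40 ± 0.84, Elovl4 by 7.60 ± 0.92 and the suprabasal keratin Krt10 by 5.01 ± 0.65. Bulge genes ranked lower, 15 called lower and 2 higher of 35 (20 and 3 adjusted over the list alone; median -1.85; camera adjusted p = 1.32e-07, adjusted p = 0.0886 with an estimated correlation). They included the Wnt receptor Fzd2 by -3.72 ± 0.59, Ptn by -2.63 ± 0.42 (355 ± 67.1 against 2189 ± 465 CPM) and the follicle transcription factor Lhx2 by -4.27 ± 0.69. Camera called 30 of 42 lists, 26 up and 4 down, of which 2 passed with an estimated correlation, 25 in fry and 23 without every library in turn.

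Lgr6 control cells were compared with the same WT Lgr5 libraries. Ly6d was higher by 11.63 ± 0.96 (3542 ± 1452 against 1.12 ± 0.501 CPM, n = 3 and 3; edgeR adjusted p = 1.94e-07), Ly6a by 10.06 ± 0.64, Krt77 by 9.42 ± 1.29, Krtdap by 8.79 ± 1.08 and the peptide hormone gene Pyy by 8.76 ± 0.75. Lgr5 was lower by -5.49 ± 1.35 (edgeR adjusted p = 0.0157), the amino acid transporter Slc38a4 by -5.82 ± 0.95, the BMP antagonist Grem1 by -5.30 ± 0.83 (12.9 ± 13.3 against 512 ± 105 CPM) and Hmcn1, a matrix gene, by -5.13 ± 0.51. Lrig1 was higher by 1.78 ± 0.50 (edgeR adjusted p = 0.0177), a call lost without WT Lgr6 replicate 3 (1.40, adjusted p = 0.159), WT Lgr5 replicate 2 (adjusted p = 0.0869) or WT Lgr5 replicate 3 (adjusted p = 0.0565). Akr1c18, higher by 9.40 ± 2.19, lost its call without any of the WT Lgr5 replicates 1, 2 and 3 (adjusted p = 0.0562, 0.0567 and 0.0544). edgeR called 3713 genes, 3236 higher and 477 lower, or 87.2% higher, against 1941 and 1725, or 52.9%, at a minimum mean CPM of 5. The median of all genes was -0.49 under TMM, -0.996 under RLE and -0.04 at that minimum. DESeq2 called 3032 higher and 3203 lower, and without WT Lgr6 replicate 3 edgeR called 1932 genes.

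Keratinocyte, histocompatibility and bulge groups were also read in Lgr6 against Lgr5 cells, with the WT Lgr5 libraries shared by both comparisons. Of the interfollicular markers 7 of 8 were called higher (7 adjusted over the list alone; median 6.00; camera adjusted p = 6.81e-12, adjusted p = 0.00165 with an estimated correlation). Of the 20 histocompatibility genes 15 were called higher (15 adjusted over the list alone; median 3.09; camera adjusted p = 1.67e-16, adjusted p = 0.00103 with an estimated correlation), with Cd74 by 7.88 ± 0.63 (192 ± 120.0 against 0.805 ± 0.264 CPM) and H2-Q6 by 5.87 ± 0.56. Bulge genes were lower, 20 called lower and 2 higher of 35 (21 and 3 adjusted over the list alone; median -2.01; camera adjusted p = 9.43e-14, adjusted p = 0.0277 with an estimated correlation), with Ptn by -3.01 ± 0.36, the matricellular gene Ccn2 by -3.30 ± 0.40 and Gas1 by -2.56 ± 0.36. Langerhans cell and macrophage markers had a median of 0.84 and T-cell markers of 1.63, where the median of all genes was -0.49. Medians were -1.45 for melanocyte, -0.82 for fibroblast and -1.35 for endothelial markers. They were -0.997 for Merkel and neural and -0.94 for blood, muscle and fat markers. Camera called 29 lists, 26 up and 3 down, of which 3 passed with an estimated correlation, 26 in fry and 21 without every library in turn.

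Ribosomal and energy genes ranked lower in Lgr5 than in Lrig1 and Lgr6 controls. Of 82 cytosolic ribosomal protein genes 41 were called higher in Lrig1 (58 adjusted over the list alone; median 1.47; camera adjusted p = 1.49e-26, adjusted p = 0.173 with an estimated correlation). In Lgr6 64 were called higher (73 adjusted over the list alone; median 1.74; camera adjusted p = 7.88e-36, adjusted p = 0.119 with an estimated correlation), led by Rpl14 by 3.57 ± 0.46 and Rpsa by 3.15 ± 0.41. Of 76 nuclear oxidative phosphorylation genes 55 were called higher in Lrig1 (63 adjusted over the list alone; camera adjusted p = 9.56e-34, adjusted p = 0.0886 with an estimated correlation). In Lgr6 they were 54 (68 adjusted over the list alone; camera adjusted p = 1.85e-31, adjusted p = 0.0981 with an estimated correlation). Uqcrc2 led in each, by 3.54 ± 0.44 and 3.61 ± 0.43. Ribosome rescue genes ranked higher in Lrig1, 5 of 28 called (7 adjusted over the list alone; median 0.76; camera adjusted p = 0.000960, adjusted p = 0.1004 with an estimated correlation), with Cnot9 by 3.73 ± 0.53 and Wdr61 by 3.42 ± 0.55. Cnot9 entered that list through its older symbol Rqcd1, and it encodes a subunit of the CCR4-NOT deadenylase rather than a rescue factor. The list was not retested without Cnot9. Pelo itself had log2 fold changes of -1.47 ± 0.87 in Lrig1 and -1.82 ± 0.77 in Lgr6 against Lgr5 (edgeR adjusted p = 0.254 and 0.139). Markers of 3 other cell types were called lower in Lrig1 against Lgr5, where the median of all genes was itself -0.99. Of 14 melanocyte markers 11 were lower in value, 1 of them called (4 adjusted over the list alone; camera adjusted p = 0.0193, adjusted p = 0.186 with an estimated correlation), namely Mitf by -2.46 ± 0.53. That call was lost without WT Lrig1 replicates 1 and 2 (adjusted p = 0.0501 and 0.0852), and the list's without WT Lrig1 replicate 2 or WT Lgr5 replicate 2 (adjusted p = 0.144 and 0.0801). Of 19 fibroblast markers 18 were lower in value, with 1 called lower and 1 higher (1 and 1 adjusted over the list alone; median -2.09; camera adjusted p = 0.0189, adjusted p = 0.439 with an estimated correlation), a call lost without WT Lrig1 replicate 2 (adjusted p = 0.0632). Of 15 endothelial markers 14 were lower in value, 0 called and 0 adjusted over the list alone (median -1.71; camera adjusted p = 0.0330, adjusted p = 0.453 with an estimated correlation). The endothelial call was lost without WT Lrig1 replicate 2 or WT Lgr5 replicate 3 (adjusted p = 0.215 and 0.0522). Merkel and neural, T-cell, Langerhans and blood, muscle and fat markers had medians of -2.11, -2.12, -1.74 and -1.51 and were not called. The Lgr5 libraries also held more satellite-like sequence, and the mean log2 CPM of the ribosomal list was 5.59 in WT Lgr5 replicate 3, 7.23 and 7.03 in replicates 1 and 2, and 8.11 to 8.90 in the 11 Lrig1 and Lgr6 libraries.

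**Figure D2:**
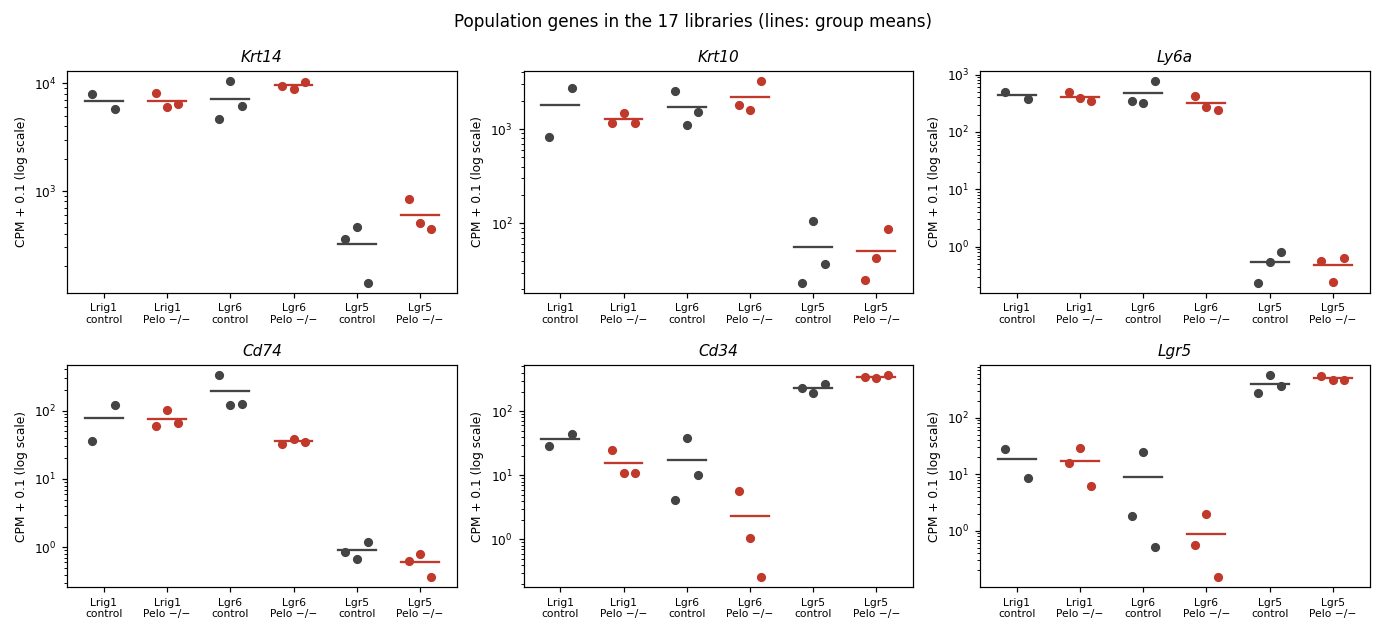
Levels of 6 genes that differ between populations, as CPM plus 0.1 on a log axis, with WT in black, Pelo -/- in red and lines at group means. Krt14 averaged 6886 ± 1568 CPM in WT Lrig1, 7133 ± 3077 CPM in WT Lgr6 and 319 ± 163 CPM in WT Lgr5 libraries (SD, n = 2, 3 and 3).

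Lrig1 and Lgr6 control cells differed in no single gene by edgeR. Among genes that the naming rule admits, the smallest p were those of the DNA repair gene Parp1, with a value of 1.96 ± 0.48 (97.5 ± 39.0 against 25.1 ± 8.38 CPM, n = 2 and 3), the lamin gene Lmna (1.48 ± 0.43) and Klhl9 (1.40 ± 0.41). Among lower genes they were the growth factor binding gene Igfbp4 (-1.96 ± 0.58), Hmga1b (-1.93 ± 0.58) and Klhl2 (-1.33 ± 0.43). edgeR called 0 of 30405 genes, with 1420 at unadjusted p < 0.05 against 1520 expected by chance, DESeq2 called 5 higher and 45 lower, and limma-voom 0. Bulge genes ranked higher in Lrig1 cells (23 of 35 higher in value, 0 called, 0 adjusted over the list alone; median 0.18; camera adjusted p = 0.000471, adjusted p = 0.830 with an estimated correlation), led by Ccn2 (0.91 ± 0.40) and Col6a1 (0.95 ± 0.48). No other list was kept without each library. Wound genes ranked lower (28 of 33 lower in value, 0 called, 0 adjusted over the list alone; camera adjusted p = 0.00720, adjusted p = 0.830 with an estimated correlation). In mean CPM the neutrophil alarmin S100a9 was at least 93.6-fold lower, without being called. The mean log2 CPM of the wound list was 1.01, 3.38 and 0.46 in WT Lgr6 replicates 1, 2 and 3. It was -0.05 and 0.14 in WT Lrig1 replicates 1 and 2. The wound call was lost without WT Lrig1 replicate 1 or WT Lgr6 replicate 2 (adjusted p = 0.237 and 0.317). Camera called 9 lists, 6 up and 3 down, of which 0 passed with an estimated correlation and 0 in fry. Without WT Lrig1 replicate 1 it called 17 lists, without WT Lrig1 replicate 2 it called 4, and without WT Lgr6 replicates 1 and 3 it called 5 and 22. The median of all genes was -0.34 under TMM and -0.22 under RLE.

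With Pelo -/- in Lrig1 cells no gene passed. Within the naming rule the smallest p were those of Zfp503, a developmental repressor, with a value of 1.71 ± 0.53 (40.3 ± 11.3 against 12.3 ± 0.530 CPM, n = 3 and 2), Zbtb24 (2.17 ± 0.67) and Klhl2 (1.32 ± 0.43). Among lower genes they were those of the ATP synthase gene Atp5s (-2.39 ± 0.58; 8.90 ± 3.54 against 46.8 ± 8.79 CPM), the prostaglandin D synthase gene Hpgds (-2.28 ± 0.70) and Zfp97 (-1.41 ± 0.46). The ribosomal gene Rpl29 had a value of 2.02 ± 0.80, the mTOR regulator Flcn 1.51 ± 0.53, the replication gene Gins2 -0.98 ± 0.51 and the kinesin gene Cenpe -1.65 ± 0.77. edgeR called 0 genes, with 1106 at unadjusted p < 0.05 against 1520 expected by chance, DESeq2 called 14 higher and 14 lower, and limma-voom 1. Without Pelo -/- Lrig1 replicate 2 edgeR called 1 gene.

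Nuclear oxidative phosphorylation genes ranked lower in Pelo -/- Lrig1 cells. The median log2 fold change was -0.28 for mitochondrial ribosomal genes and -0.06 for mitochondrially encoded genes. Of 76 oxidative phosphorylation genes 68 were lower in value, 0 called and 0 adjusted over the list alone (median -0.29; camera adjusted p = 9.34e-05, adjusted p = 0.971 with an estimated correlation), led by Ndufb7 (-1.35 ± 0.67) and Atp5o (-0.73 ± 0.42). The call was lost without WT Lrig1 replicate 2 (adjusted p = 0.977, direction reversed) or Pelo -/- Lrig1 replicate 3 (adjusted p = 0.134). Of 28 upper follicle genes 21 were lower in value, 0 called and 0 adjusted over the list alone (median -0.38; camera adjusted p = 0.00672, adjusted p = 0.904 with an estimated correlation), led by Lrig1 and the transcription factor Gata6 (-0.95 ± 0.52). The upper follicle call was lost without WT Lrig1 replicate 2 or Pelo -/- Lrig1 replicate 3 (adjusted p = 0.911 and 0.0503). T-cell markers ranked higher (12 of 15 higher in value, 0 called, 0 adjusted over the list alone; camera adjusted p = 0.00592, adjusted p = 0.904 with an estimated correlation). In mean CPM the cytotoxic granule gene Nkg7 was at least 65.4-fold and the receptor gene Tcrg-C1 at least 25.0-fold higher, and neither was called. The list's mean log2 CPM was -0.81, 0.83 and 0.43 in Pelo -/- Lrig1 replicates 1, 2 and 3. It was -1.21 and -1.73 in WT Lrig1 replicates 1 and 2. The T-cell call was lost without Pelo -/- Lrig1 replicate 2 (adjusted p = 0.0516). Camera called 6 lists, 2 up and 4 down, of which 0 passed with an estimated correlation, in fry or without every library in turn. Without WT Lrig1 replicate 1 it called 10 lists, without WT Lrig1 replicate 2 it called 1, and without Pelo -/- Lrig1 replicate 3 it called 2. By Xist and Y-linked genes 3 of 3 Pelo -/- Lrig1 libraries and 1 of 2 WT Lrig1 libraries read as male, and with sex as a covariate camera called 16 lists, 2 up and 14 down.

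In Lgr5 cells Itga3, the integrin subunit of a basal laminin receptor, rose with Pelo -/- by 2.13 ± 0.38 (log2, SE; 50.2 ± 12.4 against 11.5 ± 2.24 CPM, SD, n = 3 and 3; edgeR adjusted p = 0.0457). The call was lost without WT Lgr5 replicate 1 (2.16, adjusted p = 0.0791), replicate 2 (2.19, adjusted p = 0.0657) or replicate 3 (1.92, adjusted p = 0.127), or without Pelo -/- Lgr5 replicate 2 (1.92, adjusted p = 0.115). It was also lost with RLE (1.97, adjusted p = 0.0813), by limma-voom (2.16, adjusted p = 0.413), from only the libraries compared (2.06, adjusted p = 0.988), among protein-coding genes (2.03, adjusted p = 0.07998) and without satellite-like genes (2.07, adjusted p = 0.0869). edgeR called 6 genes, all higher, and Itga3 alone met the naming rule. Within that rule the smallest p among lower genes were those of the nucleoside kinase gene Dck (-2.50 ± 0.59, edgeR adjusted p = 0.166), Zfp280c (-1.65 ± 0.42, adjusted p = 0.254) and the replication-linked gene Wdr76 (-2.20 ± 0.56, adjusted p = 0.260). Unadjusted p < 0.05 held for 1901 genes against 1520 expected by chance. DESeq2 called 84 higher and 96 lower, limma-voom 0, and edgeR 5 higher and 2 lower at a minimum mean CPM of 5. edgeR called 52 higher and 28 lower without a filter, 26 higher and 5 lower with the replicate block and 3 higher without satellite-like genes. It called 0 from only the libraries compared and 0 among protein-coding genes, with 643 and 1195 at unadjusted p < 0.05. Without WT Lgr5 replicate 2 or Pelo -/- Lgr5 replicate 3 edgeR called 16 or 20 genes. The median of all genes was -0.14 under TMM and -0.34 under RLE.

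Immediate early genes ranked higher in Pelo -/- Lgr5 cells. Of 29 such genes, which answer to growth signals and to tissue dissociation, 27 were higher in value, 0 called and 17 adjusted over the list alone (median 1.30; camera adjusted p = 7.25e-17, adjusted p = 0.261 with an estimated correlation). They were led by Egr2 (3.77 ± 0.80; 19.5 ± 21.5 against 1.41 ± 0.636 CPM), Egr1 (2.24 ± 0.60), the phosphatase gene Dusp1 (1.61 ± 0.47) and Junb (1.88 ± 0.57). Without Pelo -/- Lgr5 replicate 3 edgeR called Egr2 (4.33, adjusted p = 0.00141) and Egr1 (2.72, adjusted p = 0.0420). The list's mean log2 CPM was 5.19, 5.18 and 4.29 in WT Lgr5 replicates 1, 2 and 3 and 6.98, 6.27 and 5.38 in Pelo -/- Lgr5. It was lowest in the library with the largest satellite-like share (25.0%) and highest in that with the smallest (1.69%), and the call was kept without either (camera adjusted p of at most 2.36e-07). Of 26 basal keratinocyte genes 22 were higher in value, 1 called and 1 adjusted over the list alone (median 0.56; camera adjusted p = 1.10e-08, adjusted p = 0.261 with an estimated correlation). First among them were Itga3, the metallothionein Mt1 (1.25 ± 0.43) and Sparc (1.15 ± 0.40). The 8 interfollicular keratinocyte markers had a median of 0.67. Among these, Krt14 stood at 836.5, 502 and 442 CPM in Pelo -/- Lgr5 and at 355, 461 and 140 CPM in WT Lgr5. Of 35 bulge genes 28 were higher in value, 0 called and 0 adjusted over the list alone (median 0.40; camera adjusted p = 1.29e-05, adjusted p = 0.261 with an estimated correlation). Bulge genes were led by the Wnt receptor Fzd3 (1.78 ± 0.66), Ccn2 (0.76 ± 0.37) and Dkk3 (0.84 ± 0.45). The immediate early, basal keratinocyte and bulge lists alone kept their calls without every library in turn. Camera called 18 lists, 16 up and 2 down, of which 0 passed with an estimated correlation and 0 in fry. Without WT Lgr5 replicate 3 it called 8 lists and without Pelo -/- Lgr5 replicate 1 it called 6.

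Ribosomal genes ranked higher and division genes lower in Pelo -/- Lgr5 cells, calls that depended on single libraries. Of 82 cytosolic ribosomal protein genes 79 were higher in value, 0 called and 1 adjusted over the list alone (median 0.55; camera adjusted p = 2.30e-14, adjusted p = 0.550 with an estimated correlation). The smallest p were those of Rpl29 (3.12 ± 0.73), Rps2 (1.43 ± 0.51) and Rps15 (1.25 ± 0.47). The call was lost without WT Lgr5 replicate 3 or Pelo -/- Lgr5 replicate 1 (adjusted p = 0.988 and 0.357). The list's mean log2 CPM was 5.59 in the former and 8.04 in the latter, against 6.56 to 7.23 in the other 4 Lgr5 libraries. Of 28 ribosome rescue genes 17 were higher in value, 0 called and 0 adjusted over the list alone (median 0.30; camera adjusted p = 0.0384, adjusted p = 0.526 with an estimated correlation). They were led by the translational GTPase gene Gtpbp2 (1.12 ± 0.51), Tcf25 (0.59 ± 0.34) and Hbs1l, the partner of Pelo (0.65 ± 0.40). The rescue call was lost without WT Lgr5 replicates 1 and 3 or Pelo -/- Lgr5 replicate 1 (adjusted p = 0.210, 0.727 and 0.626). Of 49 genes of G2 and mitosis 40 were lower in value, 0 called and 0 adjusted over the list alone (median -0.77; camera adjusted p = 0.000952, adjusted p = 0.577 with an estimated correlation), led by the spindle gene Nusap1 (-1.73 ± 0.58). That call was lost without WT Lgr5 replicates 1 and 2 or Pelo -/- Lgr5 replicates 2 and 3 (adjusted p = 0.139, 0.775, 0.138 and 0.332). The mean log2 CPM of this list was 3.95, 3.95 and 1.72 in WT Lgr5 replicates 1, 2 and 3. It was 3.59, 1.88 and 2.05 in Pelo -/- Lgr5 replicates 1, 2 and 3. High and low levels thus stood in both genotypes, and the lowest was in a WT library. Among mTOR genes Lamtor4 had a value of 2.00 ± 0.55, and the growth factor gene Hbegf of the wound list 2.36 ± 0.63 (edgeR adjusted p = 0.322 and 0.322).

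**Figure D3:**
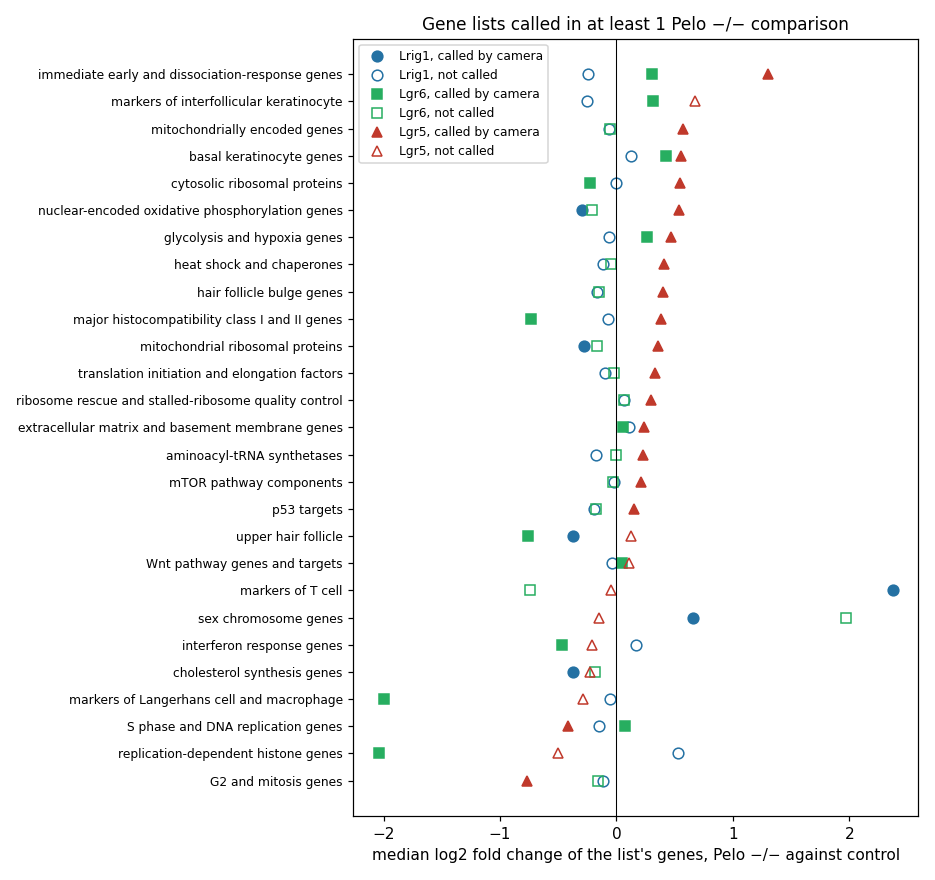
Median log2 fold change of each list called in at least 1 Pelo -/- comparison, with filled points where camera called it. The median of immediate early genes was 1.30 in Lgr5 and 0.30 in Lgr6 cells, and that of Langerhans cell and macrophage markers was -2.00 in Lgr6 cells.

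With Pelo -/- in Lgr6 cells Cd74, the invariant chain of class II molecules, had the smallest p, at -2.44 ± 0.48 (35.4 ± 3.04 against 192 ± 120.0 CPM, n = 3 and 3; edgeR adjusted p = 0.926; DESeq2 adjusted p = 0.0630). Its level was 32.4, 38.5 and 35.2 CPM in Pelo -/- libraries and 331, 121 and 125 CPM in WT. Next lower within the naming rule were the calcium sensor gene Vsnl1 (-2.02 ± 0.57) and Rbms3 (-1.64 ± 0.47), and the smallest p among higher genes were those of Armcx3 (1.55 ± 0.50), the epidermal regulator Klf3 (0.97 ± 0.35) and Parp1 (1.18 ± 0.44). Lgr5 had a value of -3.50 ± 1.30 and the collagenase gene Mmp13 of -7.28 ± 1.96 (edgeR adjusted p = 1 for each). Both rested on WT Lgr6 replicate 2, where Lgr5 stood at 24.6 CPM, and were -0.43 and -0.52 without it. edgeR called 0 genes, with 1180 at unadjusted p < 0.05 against 1520 expected by chance, DESeq2 called 3 higher and 15 lower, and limma-voom 0. The median of all genes was -0.27 under TMM and -0.16 under RLE.

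Antigen presentation genes ranked lower and basal genes higher in Pelo -/- Lgr6 cells. Of 20 histocompatibility genes 17 were lower in value, 0 called and 3 adjusted over the list alone (median -0.74; camera adjusted p = 9.57e-06, adjusted p = 0.0875 with an estimated correlation; fry adjusted p = 0.0205, a test against no change). They were led by Cd74, the class II chains H2-Aa (-1.87 ± 0.63) and H2-Ab1 (-2.38 ± 0.81) and their activator Ciita (-2.41 ± 0.92). All 19 markers of Langerhans cells and macrophages were lower in value, 0 called and 4 adjusted over the list alone (median -2.00; camera adjusted p = 5.82e-08, adjusted p = 0.110 with an estimated correlation). Outside class II the smallest p was that of Mfge8 (-2.28 ± 0.80). The lists share class II genes, whose median was -1.62 over 8 genes, against -0.20 over 11 class I genes and -1.91 over the 14 markers outside the histocompatibility list. Of 26 basal keratinocyte genes 21 were higher in value, 0 called and 0 adjusted over the list alone (median 0.43; camera adjusted p = 1.38e-11, adjusted p = 0.112 with an estimated correlation). First among them were the transcription factor Sox6 (1.15 ± 0.46) and the hemidesmosome collagen Col17a1 (0.72 ± 0.32; 2986 ± 541 against 1813 ± 229.6 CPM). These 3 lists alone kept their calls without every library in turn.

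Other lists in Lgr6 cells were less stable. Of 28 upper follicle genes 24 were lower in value, 0 called and 2 adjusted over the list alone (median -0.76; camera adjusted p = 0.00187, adjusted p = 0.409 with an estimated correlation). First were the cornified envelope gene Sprr1a (-4.89 ± 1.20) and the BMP and Wnt antagonist Sostdc1 (-1.66 ± 0.50). This call was lost without WT Lgr6 replicate 2 or Pelo -/- Lgr6 replicate 2 (adjusted p = 0.280 and 0.137). Of 82 ribosomal genes 68 were lower in value, 0 called and 0 adjusted over the list alone (median -0.23; camera adjusted p = 0.0344, adjusted p = 0.972 with an estimated correlation), led by Rps19 (-1.24 ± 0.46). That call was lost without WT Lgr6 replicate 2 or Pelo -/- Lgr6 replicates 1 and 3 (adjusted p = 0.147, 0.0566 and 0.526) and reversed without WT Lgr6 replicate 3 (adjusted p = 0.000660). Of 22 histone genes 16 were lower in value, 0 called and 1 adjusted over the list alone (median -2.04, or -1.89 with genes at their bounds; camera adjusted p = 0.0132, adjusted p = 0.409 with an estimated correlation), led by Hist1h2be (-3.98 ± 1.14). The histone call was lost without WT Lgr6 replicate 2 or Pelo -/- Lgr6 replicate 2 (adjusted p = 0.147 and 0.399). Camera called 13 lists, 7 up and 6 down, of which 0 passed with an estimated correlation and 1 in fry. Matrix and Wnt genes were called up with medians of 0.06 and 0.05 but means of -0.14 and -0.14 (camera adjusted p = 0.00398 and 0.0264, adjusted p = 0.409 and 0.409 with an estimated correlation). Without WT Lgr6 replicates 2 and 3 camera called 6 and 23 lists, and without Pelo -/- Lgr6 replicate 1 it called 8.

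The effect of Pelo -/- in Lrig1 cells was then compared with that in Lgr5 cells. Within the naming rule the negative differences with the smallest p were in the chloride channel gene Clic3 (-4.12 ± 0.78, edgeR adjusted p = 0.151), the methionine synthase reductase gene Mtrr (-3.74 ± 0.74, adjusted p = 0.151) and Tm4sf1 (-4.19 ± 0.86, adjusted p = 0.210). Positive ones were in the transaminase gene Gpt (2.35 ± 0.68), Vldlr (2.96 ± 0.88) and Ddx27 (2.54 ± 0.76). Pelo had a difference of -1.81 ± 1.12 (edgeR adjusted p = 0.957). The effect on immediate early genes ranked lower in Lrig1 than in Lgr5 cells (26 of 29 lower in value, 0 called, 11 adjusted over the list alone; median -1.34; camera adjusted p = 1.71e-13, adjusted p = 0.448 with an estimated correlation). They were led by the nuclear receptor gene Nr4a1 (-2.49 ± 0.70), Atf3 (-3.30 ± 0.97) and Egr2 (-3.59 ± 1.07). That on bulge genes ranked lower too (29 of 35 lower in value, 0 called, 0 adjusted over the list alone; median -0.50; camera adjusted p = 4.26e-05, adjusted p = 0.448 with an estimated correlation), led by Ccn2 (-1.26 ± 0.54) and Fzd3 (-2.21 ± 0.96). These 2 lists kept their calls without every library in turn. edgeR called 0 genes, with 1613 at unadjusted p < 0.05 against 1520 expected by chance, DESeq2 called 62 and limma-voom 0. Without Pelo -/- Lrig1 replicate 2, WT Lgr5 replicate 1 or Pelo -/- Lgr5 replicates 1, 2 and 3 edgeR called 1, 1, 3, 2 and 1 genes. Camera called 15 lists, 1 up and 14 down, of which 0 passed with an estimated correlation and 0 in fry. The count was 7, 5 or 9 without WT Lrig1 replicate 2, WT Lgr5 replicate 3 or Pelo -/- Lgr5 replicate 1.

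Between Lrig1 and Lgr6 cells genes of the naming rule with a small p for a difference in the effect of Pelo -/- included Cd74 (2.39 ± 0.71) and the integrin gene Itgb8 (1.91 ± 0.61). Negative differences were in Cbr4 (-1.95 ± 0.59), Atp5s (-2.51 ± 0.78) and Parp1 (-1.79 ± 0.64; edgeR adjusted p = 1 for all 5). Markers of Langerhans cells and macrophages ranked higher (17 of 19 higher in value, 0 called, 1 adjusted over the list alone; median 2.04; camera adjusted p = 0.00148, adjusted p = 0.749 with an estimated correlation), led by Cd74 and the adaptor gene Tyrobp (5.45 ± 2.20). Tyrobp was near the floor, at means of 0.174 and 1.55 CPM in WT and Pelo -/- Lrig1 and 1.46 and 0.289 CPM in WT and Pelo -/- Lgr6. Its counts there ran from 0 to 49. No list other than these markers was kept without every library in turn. Immediate early genes ranked lower (23 of 29 lower in value, 0 called, 0 adjusted over the list alone; median -0.46; camera adjusted p = 7.23e-06, adjusted p = 0.749 with an estimated correlation), led by Nr4a1 (-1.47 ± 0.70). The latter call was lost without WT Lgr6 replicate 2 (adjusted p = 0.104). edgeR called 0 genes, with 1278 at unadjusted p < 0.05 against 1520 expected by chance, DESeq2 called 52 and limma-voom 0. Without Pelo -/- Lgr6 replicate 1 edgeR called 1 gene. Camera called 14 lists, 5 up and 9 down, of which 0 passed with an estimated correlation and 0 in fry. It called 8 without Pelo -/- Lrig1 replicate 3, 8 and 5 without WT Lgr6 replicates 1 and 2, and 4 and 6 without Pelo -/- Lgr6 replicates 1 and 3.

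Between Lgr6 and Lgr5 cells the negative differences with the smallest p within the naming rule were in Tm4sf1 (-4.57 ± 0.84, edgeR adjusted p = 0.159), Clic3 (-3.75 ± 0.75, adjusted p = 0.387) and Egr2 (-4.96 ± 1.06, adjusted p = 0.483). Positive differences were in Gpt (2.95 ± 0.63), Lrrc8b (3.67 ± 0.81) and Vav3 (2.53 ± 0.58). Without Pelo -/- Lgr5 replicate 3 edgeR called Egr2 (-5.51, adjusted p = 0.00203). Histocompatibility genes ranked lower (19 of 20 lower in value, 0 called, 0 adjusted over the list alone; median -1.36; camera adjusted p = 1.29e-05, adjusted p = 0.0866 with an estimated correlation; fry adjusted p = 0.0251, a test against no change). They were led by the class I genes H2-T22 (-1.98 ± 0.62) and H2-T23 (-1.63 ± 0.59). Only this list was kept without every library in turn. Ribosomal genes ranked lower (80 of 82 lower in value, 0 called, 0 adjusted over the list alone; median -0.84; camera adjusted p = 8.17e-15, adjusted p = 0.715 with an estimated correlation), led by Rpl29 (-3.44 ± 0.98). The ribosomal call was lost without WT Lgr5 replicate 3 or Pelo -/- Lgr5 replicate 1 (adjusted p = 0.750 and 0.0950). Genes of S phase ranked higher (39 of 49 higher in value, 0 called, 0 adjusted over the list alone; median 0.55; camera adjusted p = 0.000126, adjusted p = 0.741 with an estimated correlation), led by Wdr76 (2.19 ± 0.77). The S phase call was lost without WT Lgr5 replicate 2 or Pelo -/- Lgr5 replicate 3 (adjusted p = 0.344 and 0.108). edgeR called 0 genes, with 1454 at unadjusted p < 0.05 against 1520 expected by chance, DESeq2 called 56 and limma-voom 0. Without WT Lgr5 replicates 1 and 3 or Pelo -/- Lgr5 replicates 1, 2 and 3 edgeR called 1, 1, 3, 1 and 1 genes. Camera called 15 lists, 3 up and 12 down, of which 0 passed with an estimated correlation and 1 in fry. The count was 8, 9 or 5 without WT Lgr6 replicate 3, WT Lgr5 replicate 3 or Pelo -/- Lgr5 replicate 1.

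Across 30405 genes, which are not independent replicates, the log2 fold changes of Pelo -/- were nearly unrelated between populations. Their Pearson and Spearman correlations were -0.03 and -0.02 for Lrig1 with Lgr5, -0.04 and -0.02 for Lrig1 with Lgr6, and 0.07 and 0.12 for Lgr5 with Lgr6. Each population had its own controls, so no shared library enters these values. The median SE of a gene's log2 fold change was 1.21 in Lrig1, 1.06 in Lgr5 and 1.07 in Lgr6 cells. These SE rest on 1 estimate of spread per gene over all 17 libraries, so they do not measure the spread within each population. Spearman correlations of replicates were 0.729 to 0.806 in Lgr5 and 0.887 to 0.926 elsewhere. Noise of the size of these SE keeps the correlations between populations small with or without a shared effect. They therefore do not show that the effects differed. Itga3, called in Lgr5 cells alone, differed by -1.88 ± 0.55 between Lrig1 and Lgr5 (edgeR adjusted p = 0.761), and Cd74 by 2.39 ± 0.71 between Lrig1 and Lgr6 (edgeR adjusted p = 1), so neither effect was shown to differ between populations.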

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

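Leaving out a library and the differences of effect between populations were planned. Sex as a covariate, the markers outside the histocompatibility list, the removal of satellite-like genes and the correlation with their share were tests chosen after the results were seen. For the removal of satellite-like genes and for the correlation with their share, the outcome was predicted before the test was run.

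In Lgr6 cells Cd74 averaged 35.4 ± 3.04 against 192 ± 120.0 CPM in Pelo -/- and WT libraries, and histocompatibility genes and Langerhans markers ranked lower (adjusted p = 0.0875 and 0.110 with an estimated correlation). Fewer Langerhans cells or macrophages carried into the sort could give this, and the 14 markers outside the histocompatibility list had a median of -1.911, but only 1 of them reached a mean log2 CPM of 3, so this source stays a hypothesis. A sort for GFP that also leaves out CD45-positive cells would remove it. Medians were also negative for markers of Merkel and neural cells (-0.98), fibroblasts (-0.76), T cells (-0.74) and melanocytes (-0.48). Those of blood, muscle and fat (-0.44) and of endothelial cells (-0.11) were too, while that of interfollicular keratinocytes was 0.31. The median of all genes was -0.27. A single extreme library was unlikely, since the value of Cd74 nearest to 0 was -1.793 (SE 0.489), without WT Lgr6 replicate 1, and sex as a covariate left -2.186 (SE 0.477). Lower class II expression by the Lgr6 cells themselves after loss of Pelo remains untested.

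In WT Lgr5 libraries ribosomal and oxidative phosphorylation genes ranked lower than in WT Lgr6, where the ribosomal median was 1.74 higher. The single library WT Lgr5 replicate 3 may contribute, but the median without it was 1.34 (camera adjusted p = 3.19e-21; adjusted p = 0.119 with an estimated correlation and all libraries), which argues against it as the whole cause. Without the satellite-like genes the median was 1.628, so their counts alone did not set it under TMM. TMM already trims genes with extreme ratios, so this removal could change little. It also cannot address other effects of whatever gave these counts. Lower RNA quality of the Lgr5 libraries could lower these genes, and across the 6 Lgr5 libraries the mean ribosomal level and the satellite-like share had a Spearman correlation of -0.6 (exact p = 0.242) and a Pearson correlation of -0.900 (exact p = 0.0167), or -0.155 without WT Lgr5 replicate 3 and Pelo -/- Lgr5 replicate 1. A lower ribosomal content of Lgr5 cells, and the source of the satellite-like counts, remain untested.

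In Pelo -/- Lgr5 cells ribosomal and mitochondrial lists ranked higher than in WT (0 of 18 calls kept with an estimated correlation, adjusted p = 0.550 for ribosomal genes). The single library WT Lgr5 replicate 3 may account for much of this, since the ribosomal median was 0.55 with it and 0.2597 without it (camera adjusted p = 0.988). Pelo -/- Lgr5 replicate 1 weighed on these lists too. Without it the ribosomal call was lost and camera called 6 lists, against 8 without WT Lgr5 replicate 3. The mitochondrially encoded list reversed direction without either of these libraries. These fits leave open how much of the rest is an effect of Pelo.

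All splits of the same libraries were counted, the real one included, to see how often as many calls arise. For Pelo -/- against WT in Lgr5, 8 of 10 splits gave as many genes as the real 6, with 160 as the highest other, and 4 of 10 as many lists as the real 18, with 25 as the highest other. The split with 160 genes set Pelo -/- Lgr5 replicate 1 and WT Lgr5 replicates 1 and 2 against the other 3. Its sides differed in the level of division genes. The mean log2 CPM of the G2 and mitosis list was 3.59 in Pelo -/- Lgr5 replicate 1 and 3.95 in each of WT Lgr5 replicates 1 and 2. It was 1.72 in WT Lgr5 replicate 3 and 1.88 and 2.05 in Pelo -/- Lgr5 replicates 2 and 3. What set these levels was not tested. The real split held 2 male and 1 female libraries on each side, so splits not balanced in sex are not a like measure of chance for it. In Lgr6, 5 of 10 splits gave as many lists as the real 13, with 19 as the highest other. For WT Lgr6 against WT Lgr5 only the real split reached its 3713 genes (1 of 10), with 0 as the highest other, and 2 of 10 gave as many lists as the real 29, with 30 as the highest other. With 10 possible splits the share cannot go under 0.05. For the difference between Lgr6 and Lgr5, 16 of 30 drawn splits gave as many lists as the real 15, the real one included, with 28 as the highest other, so chance was not excluded. Counts of genes test nothing where the real count is 0, since each split reaches it, 10 of 10 in Lgr6 with 1 as the highest other and 30 of 30 in the difference between Lgr6 and Lgr5 with 14.

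For the difference of the Pelo -/- effect camera called 15 lists in Lrig1 minus Lgr5, 14 in Lrig1 minus Lgr6 and 15 in Lgr6 minus Lgr5. Of these 0, 0 and 0 passed with an estimated correlation and 0, 0 and 1 in fry. For Lrig1 minus Lgr5 the camera adjusted p was 4.26e-05 for bulge genes and 1.71e-13 for immediate early genes (adjusted p = 0.448 for each with an estimated correlation). For Lrig1 minus Lgr6 it was 0.00148 for Langerhans cell and macrophage markers (adjusted p = 0.749 with an estimated correlation). For Lgr6 minus Lgr5 it was 1.29e-05 for histocompatibility genes (adjusted p = 0.0866 with an estimated correlation).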

How the results depend on the processing

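Sex as a covariate, protein-coding genes only, the fit of the 11 Lrig1 and Lgr6 libraries and the table without satellite-like genes were chosen after the data were seen. Of 165 recounts of called genes 122 stayed within 1.5-fold and 43 moved, and of 116 recounts of called lists 75 stayed and 41 moved. Among 1870 recomputed list calls 1311 were kept, 534 became weaker and 25 reversed, in 144 and 19 of 149 calls of a list in a comparison. The 25 reversals each came from leaving out a library, and an estimated correlation made 144 calls weaker and fry 96. Among 11959 recomputed values of named genes 11596 were kept, 166 became weaker, 104 stronger and 93, in 31 of 720 results, reversed. No cause of these shifts was tested. In simulated counts, changes were given only to genes at a mean log2 CPM of at least 3. Of their 2-fold changes 0% were called in the Lrig1 design and 4% in each of the Lgr5 and Lgr6 designs. Most 2-fold changes were thus out of reach. The Lgr5 libraries held down to 9647507 counts, and what depth alone limits was not tested. Another pseudocount or quantile normalization was not run, since the file holds counts.

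Called genes depended on tool and filter. For Pelo -/- in Lrig1 there were 5 (1 higher, 4 lower) without a filter, 28 (14 and 14) by DESeq2 and 1 by limma-voom. In Lgr5 there were 80 (52 and 28) without a filter, 180 (84 and 96) by DESeq2, 0 by limma-voom, 0 from only the libraries compared, 0 among protein-coding genes and 3 without satellite-like genes. In Lgr6 there were 1 without a filter and 18 (3 and 15) by DESeq2. For Lrig1 minus Lgr5 there were 25 (8 and 17) without a filter and 62 (36 and 26) by DESeq2, for Lrig1 minus Lgr6 18 (15 and 3) and 52 (45 and 7), and for Lgr6 minus Lgr5 28 (4 and 24) and 56 (26 and 30), with 1 with sex as a covariate. WT Lrig1 against Lgr5 gave 7360 by DESeq2, 5244 by limma-voom and 2152 (1689 and 463) from only the libraries compared. WT Lrig1 against Lgr6 gave 50 (5 and 45) by DESeq2, and WT Lgr6 against Lgr5 gave 6235 by DESeq2 and 2409 (1827 and 582) from only the libraries compared.

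Called lists depended on the correlation between genes. With an estimated correlation there were 0 in each Pelo -/- comparison, 0 in each difference and 0 in WT Lrig1 against Lgr6, and 2 and 3 in WT Lrig1 and WT Lgr6 against Lgr5. The fry test gave 0 for Pelo -/- in Lrig1, 0 in Lgr5 and 1 (lower) in Lgr6, 0 for Lrig1 minus Lgr5, 0 for Lrig1 minus Lgr6 and 1 (lower) for Lgr6 minus Lgr5, and 0 for WT Lrig1 against Lgr6. With sex as a covariate 16 lists (2 up, 14 down) were called for Pelo -/- in Lrig1, and 8 (4 and 4) for Lrig1 minus Lgr6 from the 11 libraries. The correlation of effects between Lrig1 and Lgr6 was 0.0212 across genes at a mean CPM of at least 5, a reversed sign. That between Lgr5 and Lgr6 fell to 0.00992 (Pearson) and 0.0109 (Spearman) across these genes.

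Replicate numbers as a block, which assumes pairing, gave 31 genes (26 higher, 5 lower) for Pelo -/- in Lgr5 and 3 (1 and 2) for Lgr6 minus Lgr5. Correlations of residuals between WT and Pelo -/- libraries of the same number were 0.0256 and 0.0873 in Lrig1 and 0.145, -0.019 and 0.184 in Lgr5. They were 0.0455, 0.126 and 0.0955 in Lgr6. In Lrig1 the numbers did not mark clear pairs. Each Lgr6 library correlated best with its own number, as did Lgr5 replicates 1 and 3 but not 2. In each Lgr5 genotype the mitochondrial share of counts fell and the protein-coding share rose from replicate 1 to 3. Replicates 1 and 2 read as male and 3 as female in each, while the satellite-like share was not ordered alike. A batch by number in Lgr5 was thus not excluded, and the main fit ignores it. With the block Itga1 reversed to -0.37 for Pelo -/- in Lrig1 and to -0.19 in Lrig1 minus Lgr5, Lgr5 to 0.49 and 0.13 in the same results, and Lgr6 to -0.16 in Lrig1 minus Lgr5.

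Other reversed values were of genes that were not called. Lgr5 for Pelo -/- in Lrig1 was 0.0145 with RLE, 0.0463 without a filter, 0.0135 by DESeq2, 0.0315 by limma-voom, 0.0424 from only the libraries compared, 0.0542 among protein-coding genes and 0.0531 from the 11 libraries, and Eif2s3y there was -0.33 with sex as a covariate. For Pelo -/- in Lgr5, Pelo was -0.0925 and Lgr6 -0.0503 at a mean CPM of at least 5, and Lgr6 -0.0867 by limma-voom. For Pelo -/- in Lgr6, Pelo was -0.0327 and Wnt7a -0.00988 by limma-voom, Lgr6 -0.17 with sex, and Lrig1 0.0263 with RLE, 0.0206 without a filter, 0.0260 by DESeq2, 0.00398 from only the libraries compared, 0.0517 among protein-coding genes and 0.0212 from the 11 libraries. In Lrig1 minus Lgr5, Lgr6 was -0.23 with sex. In Lgr6 minus Lgr5, Pelo was 0.14 with RLE, 0.18 at a mean CPM of at least 5, 0.14 by DESeq2 and 0.0949 among protein-coding genes, and Lgr6 was 0.13, 0.14, 0.13 and 0.11 in these, 0.0140 without a filter, 0.32 by limma-voom and 0.0486 from only the libraries compared. In WT Lrig1 against Lgr5, Lgr6 was -0.0630 with RLE, -0.44 at a mean CPM of at least 5 and -0.0636 by DESeq2.

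Leaving out each library in turn, called genes ranged from 0 to 1 for Pelo -/- in Lrig1, 8 to 20 in Lgr5, 0 to 3 for Lrig1 minus Lgr5, 0 to 1 for Lrig1 minus Lgr6, 0 to 3 for Lgr6 minus Lgr5, 1294 to 3883 for WT Lrig1 against Lgr5 and 1932 to 3355 for WT Lgr6 against Lgr5. Called lists ranged from 1 to 10 for Pelo -/- in Lrig1, 6 to 21 in Lgr5, 6 to 23 in Lgr6, 5 to 21 for Lrig1 minus Lgr5, 4 to 18 for Lrig1 minus Lgr6, 5 to 18 for Lgr6 minus Lgr5 and 4 to 22 for WT Lrig1 against Lgr6.

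Lists that reversed without a library had camera adjusted p over wide ranges. The opposite direction was itself called without WT Lgr6 replicate 3 for ribosomal genes with Pelo -/- in Lgr6 (adjusted p = 0.000660) and in WT Lrig1 against Lgr6 (adjusted p = 0.0183), and without WT Lgr5 replicate 3 for translation factors in Lgr6 minus Lgr5 (adjusted p = 0.0427). For Pelo -/- in Lrig1 oxidative phosphorylation ran from 9.04e-08 to 0.977. In Lgr5 mitochondrial ribosomal genes ran from 2.49e-07 to 0.988, translation factors from 1.11e-08 to 0.895, tRNA synthetases from 0.000119 to 0.988, S phase from 5.36e-12 to 0.893, oxidative phosphorylation from 9.46e-20 to 0.988, mitochondrially encoded genes from 3.26e-14 to 0.895 and matrix genes from 0.00137 to 0.988. In Lgr6 ribosomal genes ran from 6.70e-11 to 0.526. For Lrig1 minus Lgr5 ribosomal genes ran from 6.61e-20 to 0.999 and mitochondrially encoded genes from 9.87e-11 to 0.987. For Lgr6 minus Lgr5 mitochondrial ribosomal genes ran from 3.68e-06 to 0.890, translation factors from 0.000486 to 0.902, heat shock genes from 0.000523 to 0.752, oxidative phosphorylation from 1.59e-17 to 0.870 and mitochondrially encoded genes from 7.86e-10 to 0.872. In WT Lrig1 against Lgr5 genes of G2 and mitosis ran from 0.000136 to 0.687, and in WT Lrig1 against Lgr6 ribosomal genes from 3.43e-10 to 0.249 and immediate early genes from 2.74e-08 to 0.458.

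Named genes that changed sign without a library are given in log2. For Pelo -/- in Lrig1, Itga1 ran from -0.24 to 2.68, Lgr5 from -0.71 to 0.97, Lgr6 from -0.0551 to 0.61, Ly6g6c from -1.93 to 0.13, Tsix from -0.25 to 3.72, Eif2s3y from -0.20 to 14.74 and Serpinb12 from -4.45 to 3.41. The 14.74 of Eif2s3y is not a finite fold. It came without WT Lrig1 replicate 1, when the WT library left, replicate 2, read as female and had no count of this gene. In Lgr5, Pelo ran from -0.11 to 0.52, Itga1 from -1.47 to 0.78, Lgr6 from -0.36 to 0.48, Ascc1 from -0.23 to 2.40, mt-Co1 from -0.0653 to 1.58, mt-Nd4 from -0.13 to 1.12 and mt-Co2 from -0.26 to 1.12. In Lgr6, Pelo ran from -0.0771 to 0.42, Lrig1 from -0.21 to 0.29, Lgr6 from -0.22 to 0.56, Wnt7a from -1.26 to 2.38 and Krt10 from -0.0116 to 0.75. For Lrig1 minus Lgr5, Lgr5 ran from -1.01 to 0.70 and Lgr6 from -0.23 to 0.61, and for Lrig1 minus Lgr6, Lgr6 from -0.32 to 0.48 and Krt10 from -1.66 to 0.31. For Lgr6 minus Lgr5, Pelo ran from -0.43 to 0.39, Lrig1 from -0.0254 to 0.52 and Lgr6 from -0.32 to 0.51. In WT Lrig1 against Lgr5, Lgr6 ran from -0.27 to 0.61, and in WT Lrig1 against Lgr6, Itga1 ran from -2.19 to 0.11, Lrig1 from -0.39 to 0.0558 and Mmp13 from -8.07 to 0.41.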

Other observations

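The comparisons in this part were chosen after the results were seen, and genes named here lie outside the naming rule unless named before.

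The population differences seen in controls recurred in the Pelo -/- libraries. There edgeR called 2386 genes between Lrig1 and Lgr5 (1753 higher, 633 lower) and 3026 between Lgr6 and Lgr5 (2198 and 828). Of the genes called in controls 98.0% and 98.4% had the same sign. In Lrig1 against Lgr5, 1450 genes were called higher and 241 lower in both genotypes, where 159 and 12.6 would be shared by chance, and in Lgr6 against Lgr5 1815 and 293, where 234 and 13.0 would be. No gene was called in opposite directions. Ly6a was higher by 9.99 ± 0.64 in Lrig1 and 9.62 ± 0.63 in Lgr6 (log2, SE, n = 3 and 3), the interleukin receptor gene Il20ra by 8.25 ± 0.65 and 7.89 ± 0.65, and Cd74 by 7.25 ± 0.62 and 6.14 ± 0.60, while Hmcn1 was lower by 6.74 ± 0.55 in Lgr6.

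Pelo was lower in Pelo -/- Lrig1 than in Pelo -/- Lgr5 libraries by -3.28 ± 0.81 (edgeR adjusted p = 0.0115). In WT the value was -1.47 ± 0.87 (edgeR adjusted p = 0.254), and the difference between the genotypes, -1.81 ± 1.12, did not pass (edgeR adjusted p = 0.957). Among the 5 Lrig1 libraries Pelo and Lrig1 were lowest in the same ones, Pelo -/- Lrig1 replicates 2 and 3, with 0.483 and 0.857 CPM of Pelo and 7.42 and 11.6 CPM of Lrig1.

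Lrig1 and Lgr6 cells compared over both genotypes gave 0 genes called by edgeR, with 1731 at unadjusted p < 0.05. Among symbols that are not predicted identifiers, at a mean log2 CPM of at least 3, the smallest p were those of the complement regulator Cd59a (1.95 ± 0.32, edgeR adjusted p = 0.0592) and Slc38a4 (3.79 ± 0.66, edgeR adjusted p = 0.114). The mean effect of Pelo -/- over the 3 populations gave 0 genes called by edgeR, with 1509 at unadjusted p < 0.05. Itga3 was first among the same symbols (0.93 ± 0.23, edgeR adjusted p = 0.617).

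Genes called with Pelo -/- in Lgr5 cells but not named by the rule included Mtrr, of the methionine cycle, higher by 3.32 ± 0.54 (edgeR adjusted p = 0.0170), and the cell cycle inhibitor Cdkn2b, higher by 5.19 ± 0.91 (edgeR adjusted p = 0.0366). Neither was called by limma-voom (adjusted p = 0.284 and 0.171), by edgeR from only the libraries compared (adjusted p = 0.988 for each) or by edgeR among protein-coding genes (adjusted p = 0.0713 for each). The call of Mtrr was lost without WT Lgr5 replicate 1 (3.05, adjusted p = 0.0661). That of Cdkn2b was lost with RLE (adjusted p = 0.0585), without satellite-like genes (adjusted p = 0.0744), without WT Lgr5 replicates 1, 2 and 3 (5.24, 5.49 and 4.83, adjusted p = 0.0826, 0.0623 and 0.127) and without Pelo -/- Lgr5 replicate 2 (4.70, adjusted p = 0.06996).

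Xist and Y-linked genes differed between libraries of a group. By them 3 of 3 Pelo -/- Lrig1 libraries read as male and WT Lrig1 as 1 male and 1 female, and the sex chromosome list, called up for Pelo -/- in Lrig1 (median 0.66, mean -0.28, camera adjusted p = 0.0460, adjusted p = 0.904 with an estimated correlation), had an adjusted p of 0.940 with sex as a covariate. WT Lgr5 replicates 1 and 2 carried Xist at 17.2 and 9.998 CPM beside Ddx3y at 97.7 and 154 CPM. WT Lgr5 replicate 3 carried Xist at 103 and Ddx3y at 12.5 CPM, with no count of the Y-linked genes Eif2s3y and Uty. The pigment gene Dct stood at 177, 46.4 and 1.13 CPM in the Pelo -/- Lgr5 libraries and at 9.94, 39.0 and 8.91 CPM in WT Lgr5.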
